A study of Mus musculus with 6 samples.

How the data were processed

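Total RNA from mouse tissue labelled as whole hippocampus was measured on 6 Affymetrix whole-transcript expression arrays, with 3 arrays in each of 2 groups. Per the labels, C57BL/6J pups, an inbred laboratory strain, were injected under the skin with ethanol at 2.5 g/kg in 0.15 M NaCl, or with saline. There were 2 injections, 2 hours apart, on each of postnatal days 4 and 7. Each array held RNA pooled from 3 mice, and the protocol counts 18 mice, all male. The labels disagree on age: the sample characteristics and the design text give 21 days, whereas the treatment protocol gives day 70, and no test of age was made. The marker levels, which the report gives, argue against RNA of hippocampus alone but did not settle the tissue.

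The deposited table held log2 values, 1 column per array and 41345 probe rows, already summarized per probe row. The log2 scale was read from the range and the similar quartiles of the arrays. Per the labels' protocols, 200 ng of total RNA was converted to complementary DNA, labelled with biotin and hybridized. The background correction, the summarization and the normalization were not given in the sources used here, and any compression of differences they caused cannot be undone. Per the submitters' processing notes the genome build was mm 10. Gene names came from the platform annotation: 23521 rows named 1 gene, 1814 named several and 16010 were unnamed here. Of the rows naming 1 gene, 23328 had an Entrez identifier in a RefSeq gene table of the mouse build GRCm38, all with the same symbol, and gene positions are those of that table. No gene was named from a row with several. Probes of near-identical genes, such as pseudogenes and clustered receptor families, can bind each other's transcripts, so their values are uncertain.

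Every row was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate, two-sided), on the deposited values with no filter, and p-values were adjusted by Benjamini-Hochberg over all rows at a threshold of 0.05. A looser screen took rows with an unadjusted p under 0.05 and a fold of at least 1.2. Standard errors are those of the limma fit, with 4 residual degrees of freedom and 2.94 from the prior. The array was the replicate. Pooling 3 mice per array averages over animals, so the p-values measure the spread between pools, and the number of arrays limits the precision. With 3 arrays against 3, the smallest two-sided p of an exact permutation test is 0.1.

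On simulated data made from the spread of these arrays over 41345 rows, the test called 20% of 50 rows changed by 0.5 on the log2 scale, 96% of those changed by 1, 98% of those changed by 2 and 100% of those changed by 3, with 9 calls among unchanged rows. All 200 changed rows were put in together, which loosens the adjusted threshold. The noise was normal and independent between rows, with no effect shared by the rows of an array. The shares can therefore overstate what these arrays could find. In the data a row differing by -1.61 had an adjusted p of 0.857 in limma.

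There were 36 gene lists, of cell and region markers, pathways and controls, of which 34 had at least 5 measured genes and were tested. For lists, each gene was represented by its row with the highest mean, over 22180 genes. Lists were tested with camera at a preset correlation between genes of 0.01, with camera at a correlation estimated for each list, and with fry, each adjusted over the lists tested. Each list's median difference was also set against 10000 random lists of the same size matched on brightness. Lists of cerebellum, olfactory bulb, habenula and telencephalic pyramidal neuron genes were added later, for the closing section and the marker levels.

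Genes were named by a rule. As no row was called, the rule took the 12 genes with the largest difference in each direction among rows naming 1 gene, with an unadjusted p under 0.05, a mean above the median of all rows, and groups that did not overlap. Predicted genes and small RNA genes were counted and not named in that step. It then took up to 3 genes of each list with the smallest p, of which those with an unadjusted p under 0.05 are printed, except that Zic1 and a few marker genes given for their levels were chosen after their values were seen. Tcf7l2, the Y-linked genes and Xist were named in advance. The groups, the tests, the 36 lists, the naming rule and most alternatives were fixed before the data were examined. The alternatives covered the scaling between arrays, the limma prior, filters on rows, weights on arrays, the replicate number as a block, thresholds, the row chosen per gene and leaving out each array.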

Results

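The data were log2 expression values of 41345 probe rows on 6 arrays, 3 from pools of mice given ethanol as newborns and 3 from pools given saline. Each pool held 3 mice. The median value per array lay between 6.55 in ethanol array 2 and 6.66 in saline array 2. Pearson correlations between arrays, taken across rows, averaged 0.992 within ethanol, 0.988 within saline and 0.989 between the groups. Saline array 1 correlated at 0.990 to 0.992 with the ethanol arrays and at 0.987 with both other saline arrays. On the first principal component it scored -19.9, beside -15.7, -19.1 and -1.59 for ethanol arrays 1 to 3, against 32.6 and 23.7 for saline arrays 2 and 3. The Y-linked genes Uty, Kdm5d and Eif2s3y had mean values of 8.06 ± 0.06, 7.10 ± 0.13 and 7.60 ± 0.31 in ethanol (SD, n = 3) and 8.03 ± 0.11, 7.07 ± 0.14 and 7.62 ± 0.18 in saline (SD, n = 3). Xist, the RNA that coats the inactive X chromosome of females, stood at 5.09 ± 0.20 in ethanol and 5.07 ± 0.16 in saline (SD, n = 3), and none of these genes passed the test.

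For the labelled tissue, the median level was 7.36 over 16 dentate gyrus granule cell genes and 7.07 over 12 CA1 pyramidal cell genes. It was 7.79 over 17 CA3 and CA2 genes, against 7.10 for the median gene. Over the arrays these 3 lists lay at percentiles 62.0 to 74.3, 43.6 to 55.4 and 89.4 to 92.6 of random lists. The brightest CA3 and CA2 genes were Pcp4 at 12.81, Homer3 at 10.58 and Nptx1 at 9.94, and the dimmest were Iyd at 6.28 and Cpne4 at 6.16. Of these Pcp4 and Homer3 are also known from Purkinje cells of the cerebellum. Genes of cerebellar neurons, listed only after high values of Zic1 and Calb2 had been seen, had a median level of 10.34 over 22 genes. On every array that list lay at percentile 100 of random lists. Among them were Car8, a carbonic anhydrase-related protein of Purkinje cells, at 12.44, Gabra6, the GABA-A receptor subunit of cerebellar granule cells, at 12.17, and Cbln3, a granule cell synaptic organizer, at 12.11. Over 20 genes of telencephalic pyramidal neurons the median level was 7.49. They included Slc17a7, a vesicular glutamate transporter, at 10.95, the transcription factor Neurod2 at 10.58 and the kinase Camk2a at 9.76, and the transcription factors Neurod6 at 6.76, Emx1 at 6.39 and Emx2 at 5.28. Of these Slc17a7 and Neurod2 are also known from cerebellar granule cells. The astrocyte and myelinating oligodendrocyte lists had medians of 10.04 and 9.82, and the interneuron list stood at 8.73. Probes differ in how strongly they bind, so levels of different genes or lists do not rank their transcripts. Over the 6 arrays the list medians lay between 10.17 and 10.40 for the cerebellar list and between 6.98 and 7.17 for CA1. The cerebellar medians of the groups overlapped. The CA1 median was lower on every ethanol array than on any saline array, at 7.01 ± 0.02 against 7.14 ± 0.03 (SD, n = 3). So were the telencephalic median, at 7.34 ± 0.04 against 7.46 ± 0.00, and the striatum median, at 7.01 ± 0.04 against 7.09 ± 0.02 (SD, n = 3). Exact permutation tests of 3 against 3 cannot go below 0.1. For the telencephalic list the median of the gene differences was 0.00, with 10 genes higher and 10 lower. The cerebellar levels argue against RNA of hippocampus alone, as the closing section sets out. Whether the differences below are those of hippocampus was not settled by these levels.

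**Figure D1:**
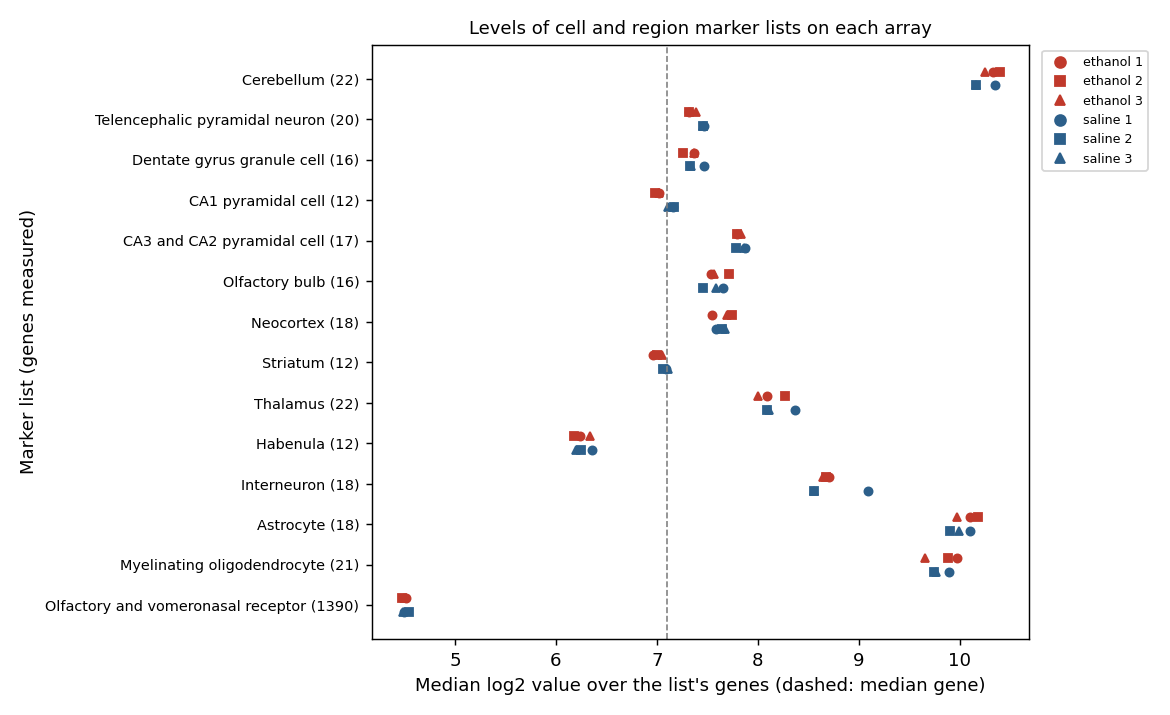
Median log2 value over the genes of each marker list (horizontal axis) on each of the 6 arrays, with ethanol arrays in red and saline arrays in blue; the dashed line is the median gene. The cerebellar list lies near 10.34 on all arrays, and the dentate gyrus, CA1 and CA3 lists lie between 6.98 and 7.87.

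The comparison of ethanol with saline asked whether exposure in the first postnatal week left differences in expression later in life. Among genes higher in ethanol were Sncg, a synuclein, by 0.42 ± 0.15 (log2 difference ± SE, 3 arrays against 3), Gng5, a G protein gamma subunit, by 0.40 ± 0.10, and Ndp, a ligand of Wnt receptors, by 0.32 ± 0.10. Among genes lower in ethanol were Rdh13, a mitochondrial retinol dehydrogenase, by -0.52 ± 0.16, Csf2rb, the shared beta chain of cytokine receptors, by -0.39 ± 0.10, and Phf11b and Phf11a, neighbouring PHD finger genes, by -0.38 ± 0.10 and -0.32 ± 0.13. None of these passed the test: limma called 0 of 41345 rows at an adjusted p under 0.05, with the smallest adjusted p at 0.857. At an unadjusted p under 0.05 there were 2290 rows, where chance alone gives 2067.25, and the fit with the replicate number as a block also called 0.

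The rule named 12 genes in each direction out of 147 that met it as higher and 94 as lower. Of the 14317 rows that could meet it, chance alone puts 715.85 at an unadjusted p under 0.05, before the demand that groups not overlap. No chance count was made for both demands together, so the counts are no sign of a yield beyond chance, nor of one below it. The other higher genes were Zfp759 (0.38 ± 0.14), the pseudogene Rpl15-ps6 (0.36 ± 0.12), the histone gene H2bc21 (0.35 ± 0.12), Ccnq (0.35 ± 0.10), Zfp617 (0.33 ± 0.11), the synaptic organizer C1ql1 (0.33 ± 0.12), Emp2 (0.33 ± 0.11), Gatc (0.32 ± 0.11) and Smg8, a part of nonsense-mediated decay (0.32 ± 0.08). The other lower genes were Btbd35f17 (-0.60 ± 0.24), Olfr1077-ps1 (-0.50 ± 0.10), Csprs (-0.42 ± 0.14), Pheta1 (-0.40 ± 0.11), Pinlyp (-0.39 ± 0.07), Erdr1 (-0.32 ± 0.08), Selenbp2 (-0.31 ± 0.12) and the pseudogene Rpl17-ps9 (-0.31 ± 0.11). Each had an adjusted p of 0.857 in limma. Gng5 and Csprs each had 3 rows naming them, and Rdh13, Ccnq and Erdr1 had 2. For these the row with the largest difference among those meeting the rule is given, and their other rows are not reported here. For Btbd35f17 saline array 2 stood at 8.70, above the other saline arrays at 7.85 and 7.76. On mouse build GRCm38, Sncg lies on chromosome 14 from 34370274 to 34374669 and Rdh13 on chromosome 7 from 4425665 to 4471280.

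**Figure D2:**
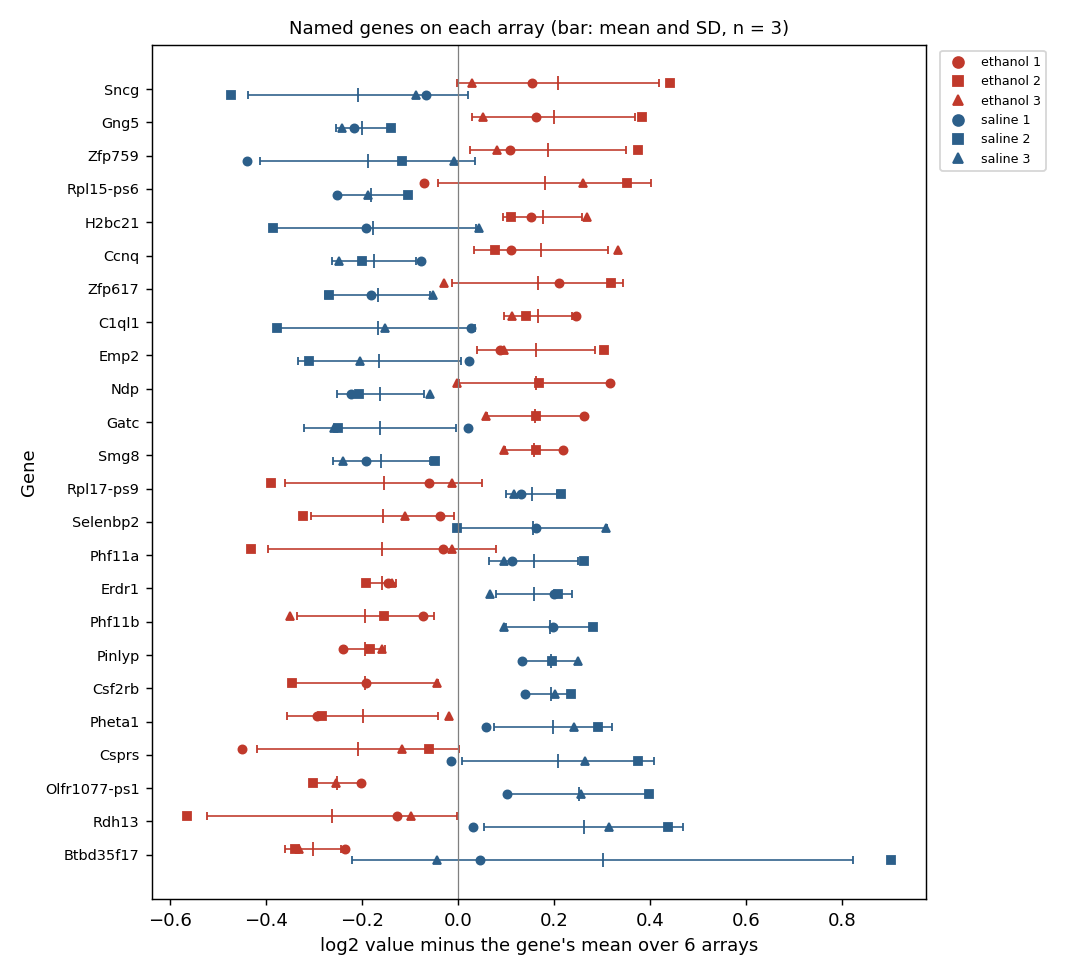
Log2 value of each named gene (vertical axis) on each array, minus the gene's mean over the 6 arrays (horizontal axis); bars are group means with SD, n = 3. The groups do not overlap for any gene, which the rule required, and the separations run from 0.60 lower for Btbd35f17 to 0.42 higher for Sncg.

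The looser screen held 580 rows higher and 1096 rows lower in ethanol. Of these, 134 higher and 291 lower rows named 1 gene, and 71.1% had no gene name here, against 38.7% of all rows. The groups did not overlap in 4575 rows, or 11.1%, where chance gives 10%. With quantile normalization it held 672 higher and 792 lower rows. With arrays centred on their medians it held 890 and 751, but centring raised the median difference of all rows from 0.00 to 0.04; every other setting tried had more lower than higher rows. Leaving out saline array 1 gave 996 higher and 2176 lower rows.

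Tcf7l2, a transcription factor of the Wnt pathway and the gene named in advance, differed by -0.48 ± 0.36 (SE, 3 arrays against 3), with an adjusted p of 0.864 in limma. Its mean was 7.08 ± 0.07 in ethanol and 7.56 ± 0.79 in saline (SD, n = 3). The wide saline spread came from saline array 1, at 8.47, whereas the highest of the other arrays was at 7.17; without saline array 1 the difference was -0.02. The gene lies on chromosome 19 from 55741797 to 55933659. Over 70 Wnt pathway genes the median difference was 0.04, with 48 higher and 22 lower, and camera did not call the list (adjusted p = 0.383). Dvl3, a Wnt signal transducer, was at 0.22 ± 0.08 and the receptor Fzd9 at -0.18 ± 0.07.

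Gene lists moved by small amounts. With a preset correlation, camera called 10 of the 34 lists, 7 higher and 3 lower in ethanol. The balance depended on the scaling: with quantile normalization 2 lists were called higher and 5 lower, and after cyclic loess 2 higher and 4 lower, with 4 of the 10 calls shared in each case. With an estimated correlation camera called 0, as did fry. At an unadjusted p under 0.05, 1 list passed camera with an estimated correlation and 0 passed fry. No list gene was called when adjusted over the list alone, nor over all rows. Genes of oxidative phosphorylation, the mitochondrial chain that makes ATP, had a median difference of 0.11 with 73 of 80 higher (camera adjusted p = 6.55e-09; adjusted p = 0.872 with an estimated correlation). Among them were Ndufa7 (0.31 ± 0.10), Ndufa1 (0.28 ± 0.10) and Cox5b (0.22 ± 0.07). Small nucleolar RNA genes, which guide the modification of ribosomal RNA, had a median of 0.23 with 61 of 73 higher (camera adjusted p = 2.84e-08; adjusted p = 0.872 with an estimated correlation), including Snord72 (0.67 ± 0.24), Snord111 (0.60 ± 0.14) and Snora73b (0.42 ± 0.15).

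Other lists called higher had 56 of 67 ribosomal protein genes higher (median 0.08), 18 of 19 cholesterol synthesis genes (0.11), 15 of 18 astrocyte genes (0.09), 26 of 29 heat shock and endoplasmic reticulum stress genes (0.08) and 30 of 36 genes of ethanol metabolism and antioxidant defence (0.07). For each of these 5 the adjusted p was 0.872 with an estimated correlation. At the preset correlation none of the 5 stayed called under quantile normalization or after cyclic loess. The astrocyte median, for 1, fell to 0.03 and 0.02 there (camera adjusted p = 0.680 and 0.811), and the ribosomal protein median to 0.06 and 0.05 (camera adjusted p = 0.0688 and 0.0904). Aqp4, the astrocyte water channel, was at 0.26 ± 0.07, and the ribosomal protein genes Rpl34 and Rpl3l went apart, at 0.23 ± 0.09 and -0.25 ± 0.10. Lists called lower were microRNA genes (308 of 483 lower, median -0.04), CA1 genes (10 of 12 lower, median -0.09) and olfactory and vomeronasal receptor genes (773 of 1390 lower, median -0.02), each with an adjusted p of 0.790 with an estimated correlation. Members with a small unadjusted p were Mir194-2 (-0.51 ± 0.10), Mir325 (-0.41 ± 0.08), Mir450-2 (-0.46 ± 0.11), the CA1 gene Fibcd1 (-0.22 ± 0.08), Olfr983 (-0.64 ± 0.11) and Vmn2r100 (0.56 ± 0.12). Of these Vmn2r100 went against the direction of its list. Both receptors were dim, with means of 3.31 in ethanol and 3.95 in saline for Olfr983 and 4.29 and 3.74 for Vmn2r100. The dimmest of 10 equal bins of genes had a mean of 3.81. The median of the receptor list was 0.01 under quantile normalization, where the list was not called (camera adjusted p = 0.811), and 0.02 under median centring, which raised all rows by a like amount and left the list called lower (camera adjusted p = 0.00637). Only 3 of the 10 list calls were shared without ethanol array 2, and 4 without saline array 2.

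**Figure D3:**
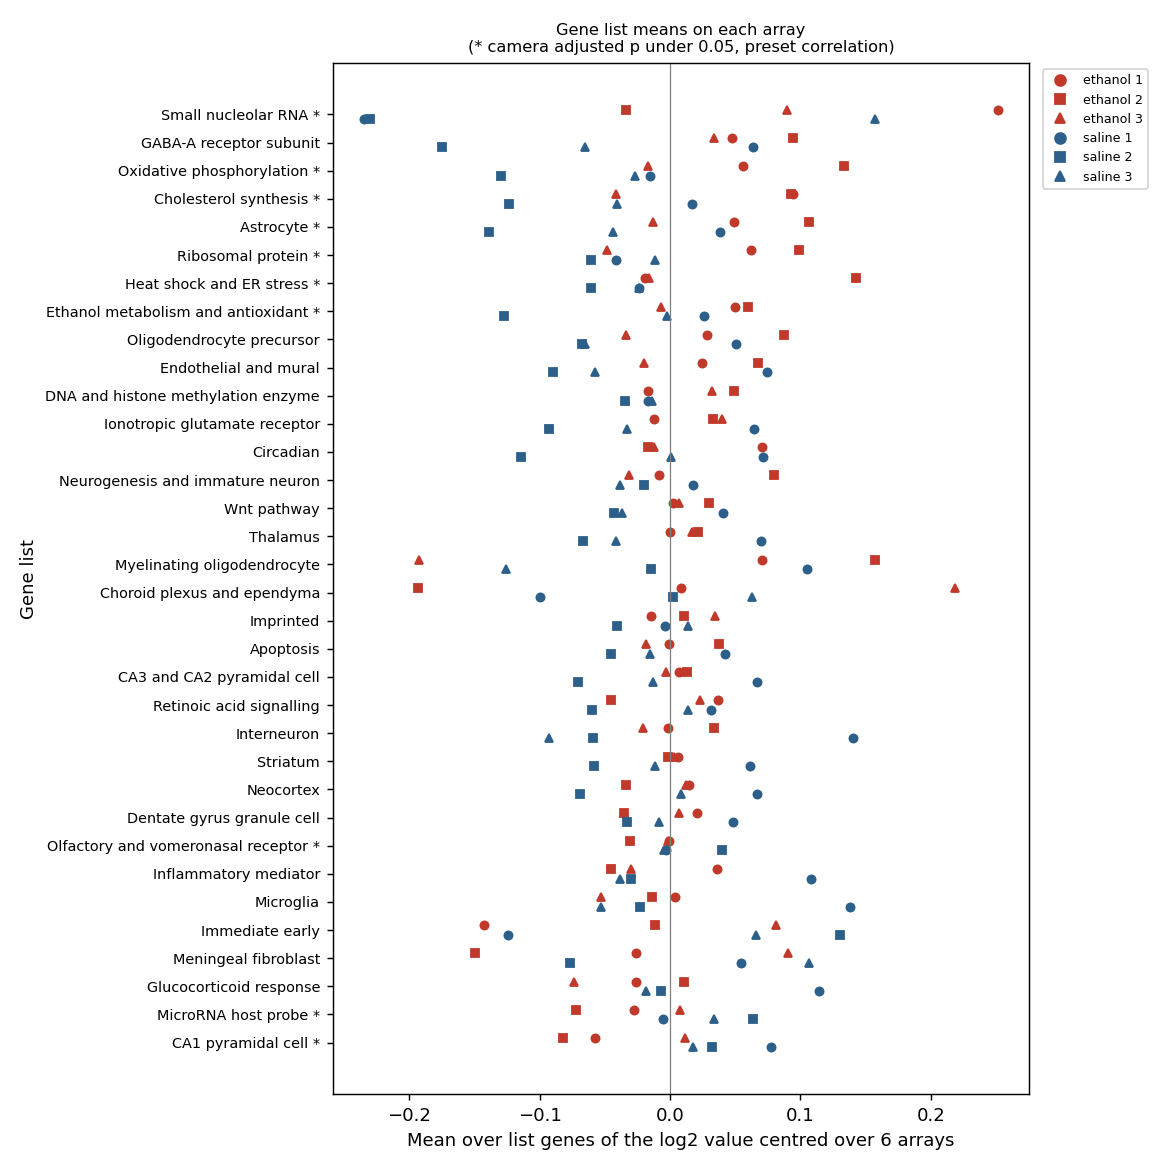
Mean over the genes of each list of the log2 value centred over the 6 arrays (horizontal axis), for each array, with ethanol in red and saline in blue. An asterisk marks the 10 lists camera called with a preset correlation; ethanol and saline arrays overlap in all but 2 lists.

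The ethanol difference moved with brightness, mostly through 1 array of each group. Over genes, the rank correlation between the ethanol difference and mean brightness was 0.375, with a median difference of 0.08 in the brightest of 10 equal bins of genes and -0.03 in the bin next to the dimmest. Genes are not independent replicates. In the brightest bin ethanol array 2 stood at 0.09 and saline array 2 at -0.11 from the mean of the arrays, whereas the other ethanol arrays, at 0.03 and 0.00, overlapped with the other saline arrays, at 0.01 and -0.03. The spread of values over rows was widest in ethanol array 2 (SD 2.03) and narrowest in saline array 2 (SD 1.97). Among random lists matched on brightness, the medians of 10 lists lay outside the middle 95%. Random genes lack the correlation between the genes of a list, so these percentiles are not tests. At the high end were small nucleolar RNA and oxidative phosphorylation at percentile 100, ribosomal protein at 99.6 and cholesterol synthesis at 98.5. At the low end were immediate early and microRNA genes at percentile 0, meningeal fibroblast at 0.01, glucocorticoid response and myelinating oligodendrocyte at 0.03 and CA1 at 0.44. Of the other called lists, astrocyte lay at 80.8, heat shock at 87.2, ethanol metabolism at 87.6 and the receptor list at 36.8.

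**Figure D4:**
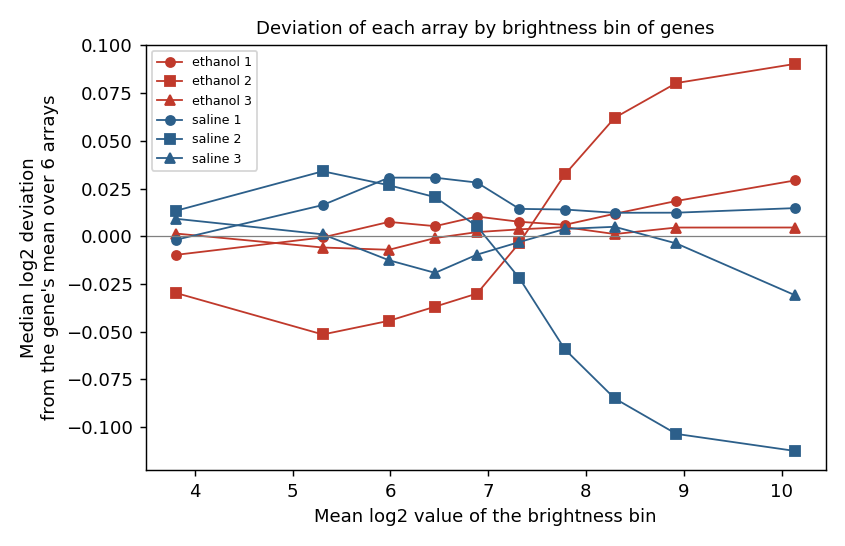
Median log2 deviation from the gene's mean over the 6 arrays (vertical axis) for 10 equal bins of genes by brightness, placed at their mean log2 value (horizontal axis), 1 line per array. Ethanol array 2 ends at 0.09 and saline array 2 at -0.11 in the brightest bin.

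The remaining 24 lists were not called. GABA-A receptor subunit genes had 12 of 13 higher with a median of 0.09 (camera adjusted p = 0.0663), and Gabra2 was at 0.59 ± 0.21 with overlapping groups. Glucocorticoid response genes had 15 of 24 lower (median -0.03; camera adjusted p = 0.0534; adjusted p = 0.872 with an estimated correlation), and camera with a preset correlation called the list in 9 of 18 other settings, quantile normalization and median centring among them, with adjusted p from 0.000635 to 0.304. Its members included Sult1a1 at -0.28 ± 0.09 and Fkbp5, a chaperone of the glucocorticoid receptor, at -0.18 ± 0.07. Microglial genes had 10 of 19 lower (median -0.02), with the purine receptor P2ry13 at -0.29 ± 0.08 and Ptprc at -0.31 ± 0.10. Immediate early genes had 17 of 29 lower (median -0.05), with Egr2 at -0.23 ± 0.08. Genes of DNA and histone methylation had 38 of 45 higher (median 0.04), with Ahcy at 0.27 ± 0.10. Oligodendrocyte precursor genes had 9 of 14 higher (median 0.03), with Vcan at 0.25 ± 0.08.

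Medians were within 0.06 of 0 in every other list tested. They were 0.02 for myelinating oligodendrocyte genes, 0.05 for endothelial and mural genes, with Tagln at -0.23 ± 0.09, 0.01 for choroid plexus and ependyma, and -0.06 for meningeal fibroblasts. Neuronal and regional lists stood at 0.03 for thalamus, with Calb2 at 0.18 ± 0.07, 0.00 for striatum and -0.00 for neocortex. The dentate gyrus list stood at -0.01, the CA3 and CA2 list at 0.04, with Iyd at -0.19 ± 0.08, interneurons at 0.03 and immature neurons at 0.00. Pathway medians were 0.04 for ionotropic glutamate receptors, 0.02 for imprinted genes, 0.05 for circadian genes, 0.01 for apoptosis, -0.00 for inflammatory mediators and 0.01 for retinoic acid signalling. The red blood cell list, with 2 genes measured, and the list of Y-linked genes and Xist were too short to test.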

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

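Removing the brightness trend by cyclic loess, leaving out the widest and the narrowest array, and counting identical rows as 1 were chosen only after the result was seen. With limma, 0 rows were called under each of the scalings, priors, filters and weights, and at adjusted p thresholds of 0.1 and 0.25; leaving out 1 array gave 0 to 1. The 1 row, called without saline replicate 3 and with no gene name here, differed by -1.86 there (adjusted p = 0.0459) and by -1.61 on all arrays (adjusted p = 0.857). Rows in the looser screen, higher and lower, numbered 890 and 751 with median centring, 672 and 792 with quantile normalization, 266 and 368 among rows above the median brightness, 190 and 378 among rows naming 1 gene, and 90 and 212 at 1.5-fold; the 1.5-fold screen admits fewer rows by construction, the 2 filters refit limma on fewer rows, so that the 190 and 378 differ from the 134 and 291 rows naming 1 gene in the fit to all rows, median centring raised the median difference of all rows from 0.00 to 0.04, which moves rows from lower to higher by construction, and the cause of the other was not tested. Leaving out 1 array gave 581 to 996 higher and 835 to 2176 lower. Lists called by camera numbered 6 after cyclic loess, 3 without the widest and narrowest arrays, 0 with estimated correlations, 0 by fry, and 5 to 15 leaving out 1 array. With camera at a preset correlation, the small nucleolar RNA list stayed called in 18 of 18 settings and oxidative phosphorylation in 17; estimated correlations and fry ended both calls. Of the lists not called, camera called glucocorticoid response in 9 of 18 settings, meningeal fibroblast and immediate early in 5 each, GABA-A receptor and choroid plexus in 3 each, microglia in 2, and myelinating oligodendrocyte and methylation enzyme in 1 each. The receptor list turned to 0.014 with quantile normalization, 0.018 with median centring and 0.00686 after cyclic loess; centring raised all rows by a like amount and left the list called lower (adjusted p = 0.00637), and the cause of the other turns was not tested. Tcf7l2 ranged from -0.74 to -0.02 leaving out 1 array. Of 893 recomputed differences of 53 named genes, 0 passed the threshold and 0 changed sign. All of these genes but Tcf7l2 were named for a small p in these same arrays, many also for groups that did not overlap. The priors, the row filters and the replicate block leave a log2 difference as it is. The lack of sign changes was thus largely fixed in advance and says little about robustness. For the 3 Y-linked genes and Xist, not chosen by p and with differences near 0, 10 of 67 changed sign, over a range of -0.22 to 0.15. The values gave no sign that arrays with the same number were paired. Correlations of deviations were 0.10, -0.06 and 0.04 for these, against -0.13 to 0.10 for arrays with unlike numbers. Whether such pools shared litters or a batch is not known. With the replicate block, limma called 0 rows, the screen held 715 and 1383, camera called 12 lists and Tcf7l2 was at -0.48. Rows near the dim end carry little signal over background, which limits small differences there.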

Other observations

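The tests of the thalamic and forebrain lists, of the probe table, of brightness-matched lists, of cyclic loess and of small RNA yield were chosen only after the result was seen; the cerebellar, olfactory bulb, habenular and telencephalic lists were written after Zic1 and Calb2 had been seen at high values, with neither in them, and before their own values were looked at. The cerebellar genes themselves moved little with ethanol. Of 22 genes, 21 were higher and 1 lower, with a median difference of 0.09, where the brightest of 10 equal bins of all genes had 0.08 (camera adjusted p = 0.0345 over the 4 added lists; adjusted p = 0.903 with an estimated correlation), and 0 passed when adjusted over the list alone or reached an unadjusted p under 0.05. The differences were -0.17 ± 0.08 for Barhl1, a transcription factor of granule cells, 0.14 ± 0.07 for Cbln3, and 0.08 ± 0.09 for Gabra6 (SE, 3 arrays against 3). Medians were 0.03 for the olfactory bulb and habenular lists and 0.00 for the telencephalic list.

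Genes of cerebellar neurons had high values on all 6 arrays labelled as hippocampus. On each array the median of the cerebellar list lay at percentile 100 of 10000 random lists and 2.71 to 3.07 above the telencephalic list. That met the condition set in advance. Yet the comparison sets levels of different probes side by side. Astrocyte and myelinating oligodendrocyte lists, of cell types found in every brain region, also lay at 100. The percentile alone therefore does not decide how much of the RNA was cerebellar. Over the arrays the CA1 list lay at percentiles 43.6 to 55.4 and the dentate gyrus list at 62.0 to 74.3. The CA3 and CA2 list lay at 89.4 to 92.6 and the telencephalic list at 67.6 to 79.8. Of the 22 cerebellar genes, 6 are also known from hippocampus, and the other 16 had a median of 10.34 with all 16 above the median gene. A probe table that pairs rows with wrong genes is argued against by the olfactory receptor list, whose median lay at percentile 0 on every array. Over the arrays the olfactory bulb list lay at percentiles 76.4 to 86.4 of random lists. It thus missed the condition set in advance for an olfactory bulb source. The condition against that source was not met either. The list lay between -0.00 and 0.39 from the telencephalic list, so that source was not settled. The 16 cerebellar genes outside the 6 also known from hippocampus had a median of 10.34, against 7.10 for the median gene. With all 16 above the median gene, they argue against RNA of hippocampus alone. Cerebellar RNA on the arrays, by dissection or by an exchanged label, may be a source. Its share and its origin stay open, since no array of known tissue was at hand. No biological explanation was tested.

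Tcf7l2 was high in saline array 1 alone, by 1.30 over the next array, as were Nrgn (by 1.63), Lcn2 (by 1.12), the pituitary gene Gh (by 0.91), Sst (by 0.88), the neutrophil gene S100a8 (by 0.77), Tfap2d (by 0.77), Stfa2l1 (by 0.76), Ptgs2 (by 0.73) and Gm8300 (by 0.70). Thalamic tissue on that array may be a source: 11 of 22 thalamic genes were highest there, which met the bound set. Of all genes 21.2% were highest there, and an exact binomial test of the count against that share gave p = 0.00257. The thalamic genes are correlated (0.192 by estimate), which makes that p too small. Among the 11 genes, the lead over the next array ran from 0.0003 for Adarb1 to 0.371 for Slc17a6, so some were near ties. The median excess of the 22 genes over the other arrays was 0.07 and 1 gene exceeded 0.5, so the count does not decide. Thalamus adjoins hippocampus and not cerebellum, so thalamic tissue and a cerebellar source would not readily come from 1 dissection, which was not tested. For habenula, 5 of 12 genes were highest there, too few to decide. Forebrain tissue stays open as well. Of 20 telencephalic genes 5 were highest there, or 25% (95% confidence interval 8.7% to 49.1%), close to the share of all genes. That met the condition against forebrain tissue, which was written after the result was seen. The median excess of the 20 genes over the other arrays was 0.03. Yet Nrgn, with the largest lead of all, is 1 of the 20 and the only 1 whose excess passed 0.5. Camk2a, also in the list, exceeded the next array by 0.41. Outside the list, Npy exceeded the next array by 0.56. The interneuron list had a median of 9.09 there against 8.55 to 8.70 on the other arrays. These values point both ways, so the count does not decide. No biological explanation was tested.

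The rank correlation of 0.375 over genes between difference and brightness was 0.0842 without the widest and narrowest arrays. The bound set in advance was written over rows, so it was not tested as written, although the value over genes lay within it. Those arrays lie in opposite groups, and a difference in spread is itself such a trend. The value of 0.0842 therefore explains nothing, and the origin of the trend stays open. For oxidative phosphorylation and for small nucleolar RNA, the medians both lay at percentile 100 of lists matched on brightness. With camera at the preset correlation both stayed called after cyclic loess, with medians of 0.05 and 0.17 (adjusted p = 0.00287 and 1.23e-05). The first had a median of 0.03 and an adjusted p of 0.0865 without the widest and narrowest arrays. Random lists lack the correlation between the genes of these lists, 0.366 and 0.468 by estimate, so the percentiles overstate the evidence. Whether the trend alone gave these shifts was not settled. Of the lists called lower, CA1 and microRNA genes also lay outside the matched lists, at percentiles 0.44 and 0. At the preset correlation both stayed called after cyclic loess, with medians of -0.08 and -0.03 (camera adjusted p = 0.0493 and 0.0226). Over 18 other settings the microRNA call was lost in 1 and the CA1 call in 5, with adjusted p up to 0.319 for CA1. Leaving out ethanol array 1 or 2, or saline array 1 or 2, each ended the CA1 call. With an estimated correlation camera called neither list (adjusted p = 0.790 for both). For small nucleolar RNA, a yield of small RNA that varied from pool to pool may contribute: array means spanned 0.391 within saline, against 0.205 between the groups, and the groups overlapped. An effect of ethanol stays open and was not separable, since estimated correlations ended the call of every list.

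Chance was assessed by the 10 splits of the 6 arrays into 3 and 3, too few for a share under 0.05. Called rows were 0 in the real split and at most 0 in the others, so all 10 splits gave as many by necessity, which says nothing about chance. Rows in the looser screen were 1676 in the real split and at most 2486 in the others, with 2 of the 10 splits as large, the real one included. Camera called 10 lists in the real split and at most 15 in the others, with 3 of the 10 splits as large, the real one included. In both cases the highest was the split that set ethanol arrays 1 and 2 with saline array 1 against the rest.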
